A study of Mus musculus with 32 samples.

How the data were processed

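Counts per gene were used as deposited, with the columns mapped to groups per the labels; every column was matched (0 unmatched) and none of the 124 pairs of libraries within a table was a duplicate (lowest chi-square per degree of freedom 12.2). Reads had been converted with bcl2fastq 2.17 and aligned with TopHat to build mm9 per the submitters' processing notes, which also name DESeq. The counting tool, annotation and strand were not given in the sources used here. Leukaemia libraries were TruSeq poly-A, and HSC libraries used a SMARTer low-input step first, per the labels. The 4 tables held 23284 (leukaemia), 24043 (bone marrow), 22803 (total-knockout fetal) and 24047 rows (f-PRDM16-knockout fetal). Spike-in entries were dropped, 92 from bone marrow with 0 counts and 92 from the f-PRDM16-knockout table with 1 count. No mitochondrially encoded genes were present. The total-knockout fetal table differed in its make-up, for a reason not given: Gm-numbered genes took 9.27 to 10.3% of its counts and at most 0.386% elsewhere, and its top gene, Cdkn2d, took 5.37 to 5.74%. It also held 26 names turned into calendar dates, 2 of them repeated.

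Leukaemia libraries were fitted together, and each HSC table on its own, since tables differ in preparation. The main analysis used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, robust quasi-likelihood F test, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of genes in the report come from that edgeR test and those of lists from limma 3.58.1 camera with a preset correlation of 0.01. DESeq2 1.42.0, camera with an estimated correlation, and limma fry served as alternatives. Differences between HSC effects were tested as interactions in a joint fit. Figures and tables used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The errors after ± are standard errors for log2 changes and SD for CPM. After filtering 12958 genes were tested in leukaemia (common biological coefficient of variation 0.253), 13495 in bone marrow (0.368), 15590 in the total-knockout fetal table (0.287) and 13631 in the f-PRDM16-knockout table (0.377).

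The 28 gene lists were fixed before the data were examined; 26 or 27 had at least 3 members in a table, and mitochondrial genes had none. Genes were named by a fixed rule. It took Prdm16, then up to 8 genes per direction with the largest change among those passing, with mean log2 CPM of at least 3 and CPM that did not overlap between both groups. Chance gives such non-overlap in 10% of genes with 3 against 3. It left out sex-linked genes and names such as Gm-numbered and Rik, and added up to 4 members of each list with the smallest p. Where fewer than 3 passed in a direction, the 3 with the smallest unadjusted p were named as not passing, and interactions took up to 5 per direction. Mpo was named after its values were seen, because it marks libraries that stand apart. A few named genes are not reported here. Genes with near-identical copies, such as Stfa1 and BC100530 or Hbb-b1 and Hbb-b2, are uncertain.

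Lists not called in any of the 7 comparisons, by their lowest adjusted p, were PRDM family and partners (0.278, median 0.10, bone marrow), TGF-beta and BMP (0.0649, -0.19, f-PRDM16 knockout; 0.0406 blocked, adjusted p = 0.643 with an estimated correlation), antioxidant (0.0943, 0.07, total knockout), mitochondrial dynamics (0.140, 0.16, bone marrow), and p53 targets (0.119, -0.10, f-PRDM16 knockout). Sex-linked transcripts were tested in the 3 HSC comparisons and not called (lowest 0.134, total knockout).

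The labels give replicate numbers but no pairing. Same-number libraries were therefore compared in the data, by the correlation of their deviations from group means. In the total-knockout fetal table it was 0.415, 0.202 and 0.626 for pairs 1, 2 and 3, and for the f-PRDM16 knockout 0.624, 0.351 and 0.519. All exceed 0.1, so blocked values stand beside fetal list calls and named genes whose call the block changed. In pair 2 of the total knockout, not every library correlated best with its own number. For the f-PRDM16 knockout the block changed no gene's call, and blocked values are given for some genes only. In interactions they are given where the block changed a call.

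Self-tests changed 200 genes 2-fold or 4-fold in simulated copies of each comparison. The share recovered at 2-fold and 4-fold was 41.8 and 87.8% for KO+EV against WT+EV (4 unchanged genes called, 12822 genes). Against KO+EV it was 37.8 and 73.0% for KO+f (2, 12800) and 44.9 and 83.8% for KO+s (5, 12802). It was 48.0 and 75.0% for KO+s against KO+f (9, 12816), and 41.2 and 78.6% for bone marrow (5, 13231). For the total and f-PRDM16 knockouts it was 26.5 and 77.9% (8, 15333) and 16.0 and 56.2% (8, 13361). The real unblocked total-knockout fit called 0 genes at a granulocyte median of 2.89, so 77.9% does not describe it. The interactions recovered 7.29 and 49.5% (3, 15630) and 7.00 and 48.5% (3, 15450). Camera called a granulocyte list shifted 2-fold and no other of the 26 lists (12793 genes). The step cannot vouch for the 85 real list calls, all lost with an estimated correlation.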

Results

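The data were RNA counts per gene from 32 mouse libraries in 10 groups of 3 or 4 independent replicates per the design text, deposited as 4 tables. Sorted MLL-AF9 leukaemia cells from moribund mice gave 12 libraries: wild-type cells with empty vector (WT+EV), Prdm16-knockout cells with empty vector (KO+EV), and knockout cells carrying f-PRDM16 (KO+f) or s-PRDM16 (KO+s). Sorted haematopoietic stem cells (HSCs) gave the other 3 tables: adult bone marrow (4 KO, 4 WT), fetal liver of the total knockout (3 KO, 3 WT), and fetal liver of the f-PRDM16 knockout (3 KO, 3 WT with their own wild types). Depth was 16.4 to 23.8 M counts in leukaemia and 22.5 to 29.3 in bone marrow. Fetal depth was 26.7 to 33.2 (total knockout) and 35.5 to 44.95 (f-PRDM16 knockout). The labels do not say whether the leukaemia replicates came from separate transductions, so the p-values measure the spread between these samples.

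Prdm16, which encodes a transcriptional regulator needed in HSCs, was close to absent in MLL-AF9 cells and very high after add-back. KO+EV held 3 counts over its 3 libraries and WT+EV 40, a ratio of 14.0 in favour of WT+EV (counting interval 4.46 to 70.8), or 0.0479 ± 0.0459 against 0.713 ± 0.284 CPM. In edgeR the KO+EV change was -3.67 ± 0.69, adjusted p = 0.0297, which no longer passed without WT_EV 1 (0.0705), WT_EV 2 (0.0531), KO_EV 1 (0.0544) or KO_EV 2 (0.0818). Add-back raised Prdm16 to 266.9 ± 55.5 CPM in KO+f and 248.2 ± 60.4 CPM in KO+s, ratios of 5378 (1840 to 26080) and 5088 (1741 to 24670) to KO+EV. Counting intervals here and below cover counting error only. The Prdm16 means of KO+s and KO+f lay within each other's SD (-0.10 ± 0.22, adjusted p = 0.819). In bone marrow Prdm16 was 30.1 ± 13.3 against 30.7 ± 17.9 CPM, libraries labelled KO against WT (-0.03 ± 0.45, adjusted p = 0.988), so Prdm16 RNA does not bear out the label. In the fetal tables it was 19.9 ± 7.49 against 34.1 ± 8.04 CPM for the total knockout (-0.77 ± 0.33, adjusted p = 1.00, and -0.82 ± 0.13, adjusted p = 0.0302 with the replicate number as block, which did not pass with both libraries numbered 1 (0.0530) or 2 (0.227) left out) and 8.03 ± 1.61 against 22.0 ± 9.63 CPM for the f-PRDM16 knockout (-1.45 ± 0.36, adjusted p = 0.999; blocked -1.38 ± 0.19, adjusted p = 0.114). A count over the whole gene cannot separate both forms or test a deletion of part of the gene.

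**Figure D1:**
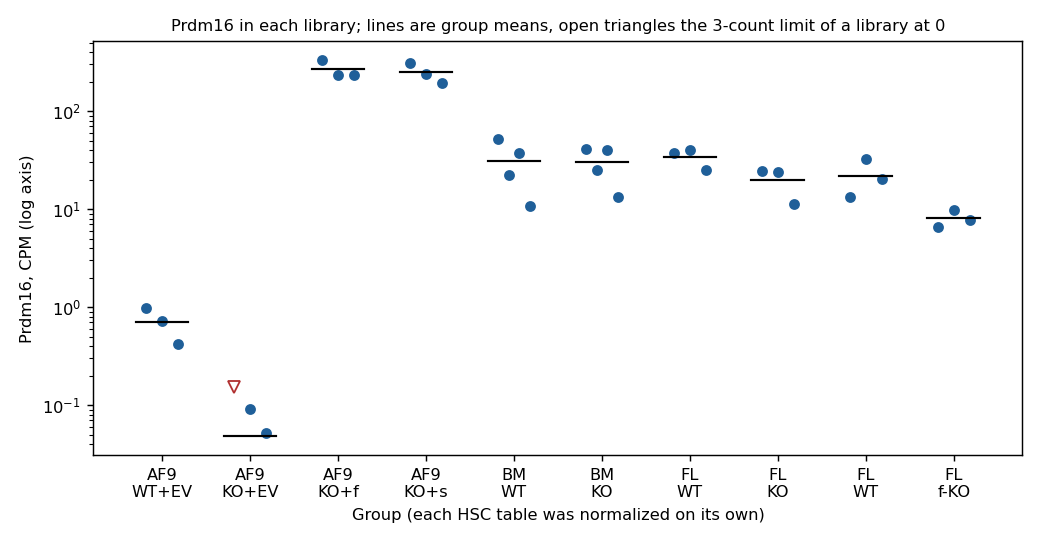
Prdm16 in CPM for each library of the 10 groups on a log axis, with lines at group means; the open triangle is the 3-count limit of a KO+EV library with 0 counts. Means ran from 0.0479 CPM in KO+EV to 266.9 CPM in KO+f.

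What changed when MLL-AF9 cells lost Prdm16? As lists, immediate early and granulocyte genes were lower in KO+EV than in WT+EV, calls lost with an estimated correlation. In edgeR 272 genes passed (117 up, 155 down, n = 3 and 3), far fewer than after add-back. At unadjusted p under 0.05 it was 2344. Immediate early and stress genes are the first transcripts made after signalling or handling. Their median log2 change was -2.002 over 24 members (camera adjusted p = 2.1e-17, 0.447 with an estimated correlation). In that list 5 members fell and 0 rose, and 16 fell when adjusted over the list alone. Egr1 fell to 20.7 ± 16.2 against 209.6 ± 139 CPM (-3.34 ± 0.65, adjusted p = 0.0343), Nr4a1 to 8.27 ± 3.33 against 38.6 ± 15.7 CPM (-2.22 ± 0.37, adjusted p = 0.0196) and Ier2 to 97.5 ± 20.2 against 259 ± 84.4 CPM (-1.41 ± 0.24, adjusted p = 0.0196). Atf3 (-4.01 ± 0.68, adjusted p = 0.0237) and Ier5 (-1.70 ± 0.32, adjusted p = 0.0297) fell. Egr1 is also the 1 member of the HSC identity list that fell. That list was not called (adjusted p = 0.750, median 0.00, mean 0.03, test direction down).

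Granulocyte genes, many of them granule and antimicrobial proteins, went down as a list with some members against it. The median was -1.20 (adjusted p = 5.3e-06, 0.447 with an estimated correlation). In this list 1 member rose and 9 fell, against 5 and 13 when adjusted over the list alone. S100a9 fell to 134 ± 32.5 against 883 ± 478 CPM (-2.72 ± 0.45, adjusted p = 0.0196), Mmp9 to 17.5 against 121 CPM (-2.78 ± 0.47, adjusted p = 0.0237) and Itgb2l to 11.2 against 70.5 CPM (-2.66 ± 0.39, adjusted p = 0.0121). Olfm4 (-3.90 ± 0.70, adjusted p = 0.0297), Stfa1 (-3.86 ± 0.74, adjusted p = 0.0324) and BC100530 (-4.03 ± 0.74, adjusted p = 0.0306) fell too, the last 2 with reads that may be shared between near-identical copies. Mpo, a granule gene of early granulocytic and monocytic cells, stood at 33200 CPM in KO_EV 3 and at 3270 and 3889 CPM in the other KO+EV libraries. Inflammation and NF-kB genes had a median of -0.46 (adjusted p = 0.000902, 0.447 with an estimated correlation). In this list 1 member rose and 4 fell, against 6 and 16 when adjusted over the list alone. Nlrp3 (-3.71 ± 0.68, adjusted p = 0.0306), Tnf (-1.64 ± 0.31, adjusted p = 0.0297) and Ptgs2 (-2.67 ± 0.55, adjusted p = 0.0361) fell, while Ccl9 rose (1.35 ± 0.29, adjusted p = 0.0439). Monocyte and macrophage genes had a median of -0.43 (adjusted p = 0.00103, 0.447 with an estimated correlation). In this list 1 member rose and 1 fell, against 1 and 8 when adjusted over the list alone.

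Replication histones were lower as a list (median -0.99, adjusted p = 6.6e-08, 0.447 with an estimated correlation). Of its 38 members 0 passed. Ribosomal protein genes had a median of -0.22 (adjusted p = 0.000902, 0.826 with an estimated correlation). There too 0 members passed. Interferon response genes were higher, median 0.25 (adjusted p = 0.000930, 0.809 with an estimated correlation). Irgm1 was the 1 member that passed (0.73 ± 0.13, adjusted p = 0.0244), against 7 up when adjusted over the list alone. Proliferation genes had a median of 0.09 (adjusted p = 0.0387, 0.826 with an estimated correlation). Plk1 (0.78 ± 0.15, adjusted p = 0.0319) and Ube2c (0.59 ± 0.14, adjusted p = 0.04996) rose, against 3 members when adjusted over the list alone. The MLL-AF9 programme was not called (median 0.06, adjusted p = 0.817, 0 of 24 members passing).

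Among genes without overlap between libraries the most raised were Clec3a (8.29 ± 1.86, adjusted p = 0.0486), C1qtnf6 (4.04 ± 0.88, adjusted p = 0.0450), F13a1 (3.44 ± 0.69, adjusted p = 0.0362), Mtmr7 (3.25 ± 0.44, adjusted p = 0.00854), Galnt7 (3.21 ± 0.63, adjusted p = 0.0352) and Pros1 (3.09 ± 0.56, adjusted p = 0.0295). The most lowered were Zc3h12c (-5.33 ± 0.87, adjusted p = 0.0196, 2.40 ± 2.67 against 96.2 ± 64.0 CPM), Zfp783 (-5.31 ± 0.64, adjusted p = 0.00729, 0.590 ± 0.106 against 23.7 ± 3.78 CPM) and Dmc1 (-4.08 ± 0.64, adjusted p = 0.0196). Clec3a was 1.98, 1.65 and 116.4 CPM in the 3 KO+EV libraries, and its value without KO_EV 3 was 3.83 with an adjusted p of 0.0310.

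Leaving out 1 library left 26 genes (14 up, 12 down, without KO_EV 2), 53 (13 and 40, WT_EV 3), 100 (19 and 81, WT_EV 1), 156 (63 and 93, KO_EV 1), 162 (67 and 95, WT_EV 2) or 425 (249 and 176, KO_EV 3), so the majority was up without KO_EV 2 or 3. DESeq2 called 907, and a fit of these 2 groups alone called 1. Of 33 named genes that passed, Mtmr7, Cyp4v3, Zfp783 and Itgb2l passed in every leave-one-out fit. The number was 15, 19 and 8 without WT_EV 1, 2 and 3, and 16, 4 and 25 without KO_EV 1, 2 and 3. The interferon call ended without WT_EV 3 (0.161) or KO_EV 2 (0.139), the ribosomal call without WT_EV 1 (0.135). The proliferation call ended without WT_EV 2 (0.0813), WT_EV 3 (0.592), KO_EV 2 (0.0694) or KO_EV 3 (0.156).

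What did f-PRDM16 change in knockout leukaemia cells? KO+f had higher HSC, class II and immediate early genes and lower proliferation, oxidative phosphorylation and glycolysis genes than KO+EV as lists. Each call ended with an estimated correlation. In edgeR 1461 genes passed (892 up, 569 down, n = 3 and 3). HSC identity genes had a median of 0.70 over 25 members (adjusted p = 0.00115, 0.298 with an estimated correlation). In this list 5 members rose and 1 fell, against 6 and 2 when adjusted over the list alone. Hlf rose to 15.1 ± 6.25 against 0.895 ± 0.693 CPM (4.07 ± 0.58, adjusted p = 0.00278), Gata2 to 42.5 ± 7.88 against 2.78 ± 2.94 CPM (3.93 ± 0.77, adjusted p = 0.0116) and Cdkn1c to 43.5 against 18.3 CPM (1.25 ± 0.27, adjusted p = 0.0157). Hlf and Gata2 encode transcription factors of stem and progenitor cells, and Cdkn1c a cell-cycle inhibitor. MHC class II genes had a median of 1.17 over 11 members (adjusted p = 0.000356, 0.298 with an estimated correlation). Of these 5 rose and 0 fell (6 and 0 when adjusted over the list alone). H2-Aa rose (2.47 ± 0.50, adjusted p = 0.0132), and so did Ciita, their transcriptional activator (3.38 ± 0.74, adjusted p = 0.0166).

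Immediate early genes went up with f-PRDM16, median 1.16 (adjusted p = 0.000275, 0.535 with an estimated correlation). In this list 6 members rose and 0 fell, against 9 and 0 when adjusted over the list alone. Nr4a1 rose to 31.9 against 8.27 CPM (1.95 ± 0.37, adjusted p = 0.00892), Dusp2 to 95.5 against 21.3 CPM (2.16 ± 0.43, adjusted p = 0.0121), and Ier2 rose (1.04 ± 0.24, adjusted p = 0.0191). Inflammation and NF-kB genes had a median of 0.83 (adjusted p = 0.00115, 0.298 with an estimated correlation). In this list 10 members rose and 3 fell, against 18 and 4 when adjusted over the list alone. Nfkb1 (0.85 ± 0.12, adjusted p = 0.00286), Il1r2 (2.37 ± 0.45, adjusted p = 0.00861) and Nlrp3 (3.45 ± 0.68, adjusted p = 0.0117) rose. Monocyte and macrophage genes had a median of 0.66 (adjusted p = 0.00240, 0.298 with an estimated correlation). In this list 6 members rose and 1 fell (7 and 1 when adjusted over the list alone). Cx3cr1 (3.56 ± 0.51, adjusted p = 0.00307) and Ctss (2.40 ± 0.40, adjusted p = 0.00611) rose and the iron exporter gene Slc40a1 fell (-1.35 ± 0.28, adjusted p = 0.0130). Granulocyte genes were not called (adjusted p = 0.701, median -0.04, mean 0.13). Of its members 4 rose and 2 fell. Chi3l1 rose (2.172 ± 0.37, adjusted p = 0.00615), and Cebpa and Gfi1, which encode transcription factors, fell (-0.77 ± 0.20, adjusted p = 0.0328 and -0.63 ± 0.16, adjusted p = 0.0309).

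Megakaryocyte and platelet genes had a median of 1.21 (adjusted p = 0.00181, 0.298 with an estimated correlation). In this list 3 members rose and 0 fell (8 and 0 when adjusted over the list alone). Itga2b (3.31 ± 0.59, adjusted p = 0.00695) and Zfpm1 (2.38 ± 0.53, adjusted p = 0.0180) rose. Erythroid genes had a median of 1.52 (adjusted p = 0.000572, 0.237 with an estimated correlation). In this list 3 members rose and 0 fell (5 and 0 when adjusted over the list alone). Hemgn rose (2.59 ± 0.51, adjusted p = 0.0106) and Car1 stood at a ratio of 54.12 to KO+EV (14.64 to 452.3). Proliferation genes were lower, median -0.41 (adjusted p = 1.0e-07, adjusted p = 0.298 with an estimated correlation). In this list 0 members rose and 8 fell, against 1 and 25 when adjusted over the list alone. Plk1 fell to 70.4 against 115 CPM (-0.71 ± 0.15, adjusted p = 0.0156), Mcm3 to 324 against 521 CPM (-0.68 ± 0.16, adjusted p = 0.0205) and Rrm2 fell (-0.76 ± 0.17, adjusted p = 0.0186). Oxidative phosphorylation genes had a median of -0.27 (adjusted p = 1.2e-05, 0.535 with an estimated correlation). In this list 0 members rose and 6 fell (0 and 2 when adjusted over the list alone). Sdha fell (-0.50 ± 0.10, adjusted p = 0.0144). Glycolysis genes had a median of -0.26 (adjusted p = 0.00752, 0.237 with an estimated correlation). In this list 0 members rose and 4 fell by either adjustment. Hk2 (-0.86 ± 0.19, adjusted p = 0.0156) and Slc16a3 (-1.02 ± 0.21, adjusted p = 0.0114) fell. The list's call ended without KO_f 3 (0.0571).

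The MLL-AF9 programme was not called (adjusted p = 0.618), with 2 members up and 2 down. Mef2c rose to 513 ± 124 against 35.3 ± 29.3 CPM (3.86 ± 0.56, adjusted p = 0.00385) and Bcl2 to 84.9 against 12.98 CPM (2.71 ± 0.51, adjusted p = 0.00957). Psip1 fell (-0.56 ± 0.15, adjusted p = 0.0309). Among other genes Dennd5b (7.14 ± 0.32, adjusted p = 3.5e-07), Strc (6.54 ± 0.81, adjusted p = 0.00169), Dsp (5.61 ± 0.89, adjusted p = 0.00546) and Zc3h12c (5.19 ± 0.87, adjusted p = 0.00615) were among those that rose most, with Pcdh11x at a ratio of 252.1 (69.44 to 2087). Clec3a (-6.96 ± 1.67, adjusted p = 0.0250), C1qtnf6 (-3.24 ± 0.84, adjusted p = 0.0325), Cst7 (-3.01 ± 0.54, adjusted p = 0.00813), Mtmr7 (-2.97 ± 0.43, adjusted p = 0.00303) and Hdc (-2.81 ± 0.69, adjusted p = 0.0275) fell most. The Clec3a value without KO_EV 3 was -2.50 with an adjusted p of 0.0585. The gene count was 563 without KO_EV 2, 932 without KO_EV 3, 698 without KO_f 1 and 559 without KO_f 2, against 2267 in DESeq2 and 392 in a fit of these 2 groups alone. Of 79 named genes that passed, 26 passed in every leave-one-out fit, including Hlf, Mef2c, Bcl2, H2-Aa, Nr4a1, Nfkb1, Cx3cr1 and Hk2. The number was 70, 41 and 55 without KO_EV 1, 2 and 3, and 39, 39 and 71 without KO_f 1, 2 and 3.

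What did s-PRDM16 change in knockout leukaemia cells? KO+s changed more genes than any other leukaemia group, with granulocyte, inflammation and immediate early genes up and proliferation and oxidative phosphorylation genes down as lists. Each list call ended with an estimated correlation. In edgeR 4200 genes passed against KO+EV (2054 up, 2146 down, n = 3 and 3). Granulocyte genes had a median of 1.67 (adjusted p = 7.6e-08, 0.375 with an estimated correlation). In this list 18 of 31 members rose and 1 fell, against 19 and 3 when adjusted over the list alone. S100a9 rose to 3740.0 ± 1721 against 134 ± 32.5 CPM (4.81 ± 0.49, adjusted p = 0.000142), Lyz2 to 1812 ± 669.9 against 226 ± 34.3 CPM (3.00 ± 0.34, adjusted p = 0.000222), Chi3l1 to 72.3 ± 9.93 against 1.75 ± 0.617 CPM (5.35 ± 0.41, adjusted p = 3.3e-05) and Itgb2l to 119 against 11.2 CPM (3.41 ± 0.40, adjusted p = 0.000251). Inflammation and NF-kB genes had a median of 1.28 (adjusted p = 2.3e-05, 0.375 with an estimated correlation). In this list 24 members rose and 6 fell (26 and 6 when adjusted over the list alone). Il1r2 (3.48 ± 0.46, adjusted p = 0.000465), Tnfaip2 (1.28 ± 0.18, adjusted p = 0.000591) and Nfkb1 (0.91 ± 0.12, adjusted p = 0.000512) rose. Monocyte and macrophage genes had a median of 0.68 (adjusted p = 0.00205, 0.375 with an estimated correlation). In this list 13 members rose and 4 fell by either adjustment. Cx3cr1 (4.84 ± 0.53, adjusted p = 0.000193), Cybb (4.25 ± 0.67, adjusted p = 0.00125) and Itgam (1.17 ± 0.15, adjusted p = 0.000374) rose. Counts over the list alone for immediate early genes were 16 up and 0 down, beside 15 and 0 over all genes, with a median of 1.97 (adjusted p = 3.5e-07, adjusted p = 0.452 with an estimated correlation). Ier5 (2.60 ± 0.33, adjusted p = 0.000369), Ier2 (1.58 ± 0.24, adjusted p = 0.000883), Ier3 (1.97 ± 0.31, adjusted p = 0.00110) and Atf3 (4.01 ± 0.68, adjusted p = 0.00185) rose.

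Proliferation genes fell broadly: 1 up and 29 down of 38 (1 and 30 when adjusted over the list alone), median -0.68 (adjusted p = 8.8e-10, adjusted p = 0.383 with an estimated correlation). Aurkb fell to 69.8 ± 4.2 against 153 ± 9.23 CPM (-1.13 ± 0.16, adjusted p = 0.000643), Plk1 to 55.2 against 115 CPM (-1.06 ± 0.15, adjusted p = 0.000757) and Bub1b to 133 against 292 CPM (-1.13 ± 0.17, adjusted p = 0.000905), all of them genes of mitosis. Oxidative phosphorylation genes had a median of -0.41 (adjusted p = 1.5e-06, 0.706 with an estimated correlation). In this list 0 of 74 members rose and 32 fell (0 and 33 when adjusted over the list alone). Sdha (-0.81 ± 0.11, adjusted p = 0.000417) and Atp5b (-0.91 ± 0.15, adjusted p = 0.00110) fell. Megakaryocyte and platelet genes had a median of 1.67 (adjusted p = 0.00253, 0.375 with an estimated correlation). In this list 8 members rose and 0 fell (11 and 0 when adjusted over the list alone). F5 (1.98 ± 0.34, adjusted p = 0.00179), Gp9 (4.61 ± 0.85, adjusted p = 0.00249) and Vwf (2.59 ± 0.64, adjusted p = 0.0107) rose. HSC identity genes had a median of 0.90 (adjusted p = 0.0188, 0.452 with an estimated correlation). In this list 10 members rose and 2 fell by either adjustment, and the call ended without KO_EV 3 (0.0984). Cdkn1c rose to 124 ± 24.2 against 18.3 ± 6.50 CPM (2.76 ± 0.28, adjusted p = 0.000123) and Hlf to 5.83 against 0.895 CPM (2.70 ± 0.56, adjusted p = 0.00406). Gprasp2 went the other way to 0.931 ± 0.181 against 114 ± 57.9 CPM (-6.93 ± 0.74, adjusted p = 0.000192).

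MHC class II genes were not called (adjusted p = 0.0664), with 5 up and 1 down. H2-Aa (3.09 ± 0.51, adjusted p = 0.00158) and Cd74 (3.03 ± 0.59, adjusted p = 0.00352) rose and H2-DMa fell (-1.04 ± 0.20, adjusted p = 0.00306). Erythroid genes were not called either (adjusted p = 0.0664, 4 up, 0 down). The MLL-AF9 programme was not called (adjusted p = 0.885) and its members went both ways, 4 up and 7 down. Mef2c rose to 722 ± 36.4 against 35.3 ± 29.3 CPM (4.35 ± 0.58, adjusted p = 0.000584) and Bcl2 rose (2.53 ± 0.50, adjusted p = 0.00392). Pbx3 fell to 11.2 against 179.7 CPM (-3.999 ± 0.70, adjusted p = 0.00204). Fetal programme genes Lin28a (-4.68 ± 0.61, adjusted p = 0.000536, 2.50 ± 1.03 against 64.6 ± 6.23 CPM) and Igf2bp3 (-1.47 ± 0.20, adjusted p = 0.000591) fell, as did Sod1, an antioxidant enzyme (-1.06 ± 0.12, adjusted p = 0.000205). Dennd5b (8.51 ± 0.33, adjusted p = 5.8e-08), Strc (8.34 ± 0.83, adjusted p = 0.000138), Fam123a (7.46 ± 0.70, adjusted p = 9.3e-05) and Dsp (6.58 ± 0.93, adjusted p = 0.000792) were among the genes that rose most. Col6a3 (-9.90 ± 1.10, adjusted p = 0.000231) and Gcnt4 (-6.99 ± 1.01, adjusted p = 0.000847) were among those that fell most. KO+EV exceeded KO+s by ratios of 2315 for Clec3a (415 to 91460), 1624 for Stra6 (555.4 to 7879) and 788.6 for Dlk1 (269.5 to 3827). Clec3a without KO_EV 3 was -6.34 with an adjusted p of 0.00167. The gene count was 2732 without KO_s 1 (1413 up, 1319 down), and more genes rose than fell without KO_s 2 (1853 and 1644), KO_s 3 (1636 and 1617) or KO_EV 3 (1913 and 1908) as well. Of 104 named genes that passed, 87 did so in every leave-one-out fit.

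**Figure D2:**
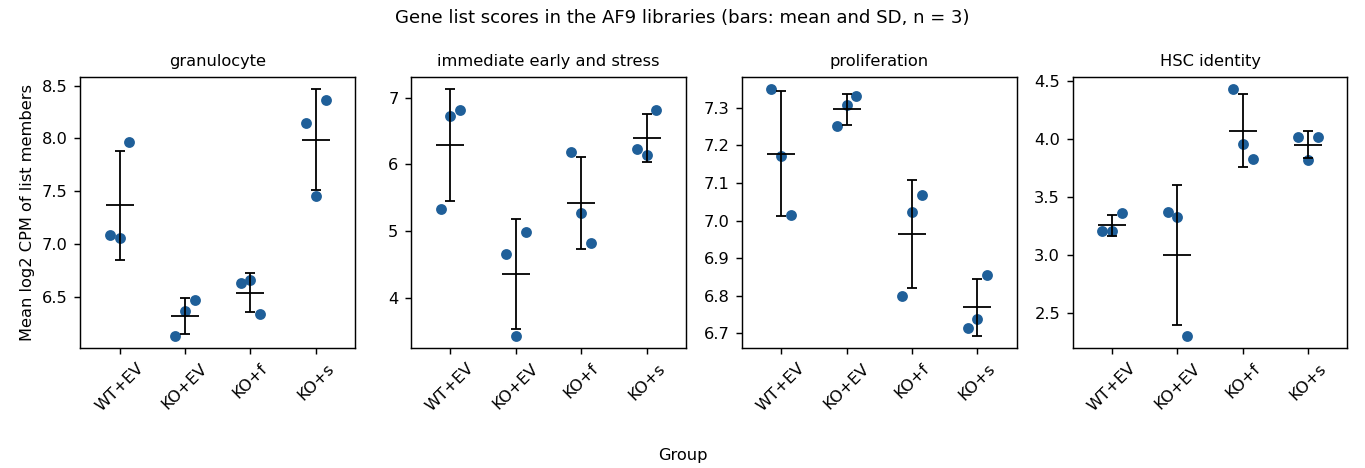
Mean log2 CPM of list members per leukaemia library (points) with group mean and SD (n = 3), in the panels granulocyte, immediate early and stress, proliferation, and HSC identity. Granulocyte scores were 6.32 ± 0.17 in KO+EV, 6.54 ± 0.18 in KO+f and 7.99 ± 0.48 in KO+s, and WT+EV stood at 7.37 ± 0.52.

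How did the s-PRDM16 cells differ from the f-PRDM16 cells? Granulocyte genes were higher in KO+s than in KO+f as a list, a call lost with an estimated correlation. Among the lists it had the largest median and the smallest camera p. In edgeR 494 genes passed (266 up in KO+s, 228 down, n = 3 and 3). The granulocyte median was 1.47 (adjusted p = 6.1e-19, 0.102 with an estimated correlation). Of 31 members 12 rose and 0 fell, against 18 and 0 when adjusted over the list alone. The list score was higher in KO+s by 1.45 (exact two-sided permutation p = 0.1, the smallest 3 against 3 can give). S100a9 (3740.0 ± 1721 against 339 ± 77.9 CPM, 3.46 ± 0.46, adjusted p = 0.00592), S100a8 (3.35 ± 0.54, adjusted p = 0.0122) and Ltf (229.8 ± 110.5 against 15.7 ± 4.70 CPM, 3.87 ± 0.84, adjusted p = 0.0343) were higher in KO+s. Lyz2 (2.49 ± 0.33, adjusted p = 0.00592), Csf3r (493 ± 66.7 against 189 ± 42.8 CPM, 1.38 ± 0.16, adjusted p = 0.00489) and Chi3l1 (72.3 against 7.96 CPM, 3.18 ± 0.36, adjusted p = 0.00489) were higher as well. Itgam (1.17 ± 0.15, adjusted p = 0.00489) and Emr1 (1.75 ± 0.33, adjusted p = 0.0199), markers of mature myeloid cells, were higher too. Both belong to the monocyte and macrophage list, which was not called (median 0.04, adjusted p = 0.188; 3 members up and 0 down, or 3 and 1 when adjusted over the list alone).

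Inflammation and NF-kB genes had a median of 0.40 (adjusted p = 0.00464, 0.737 with an estimated correlation). In this list 4 members rose and 0 fell (5 and 1 when adjusted over the list alone). Tnfaip2 (1.16 ± 0.18, adjusted p = 0.00832) and Tnf (1.57 ± 0.31, adjusted p = 0.0208) were higher in KO+s. Interferon response genes had a median of 0.25 (adjusted p = 0.0121, 0.884 with an estimated correlation). In this list 2 members rose and 0 fell (2 and 1 when adjusted over the list alone). Ddx58 was higher in KO+s (1.34 ± 0.15, adjusted p = 0.00489). The interferon call ended without KO_f 2 (0.0583) or KO_s 3 (0.0704). Immediate early genes had a median of 0.87 (adjusted p = 0.000405, 0.751 with an estimated correlation). Ier5 was the 1 member that passed by either adjustment (1.41 ± 0.31, adjusted p = 0.0341). Glycolysis genes had a median of 0.28 (adjusted p = 0.0198, 0.151 with an estimated correlation). In this list 1 member rose and 0 fell (4 and 1 when adjusted over the list alone). That member was the glucose transporter gene Slc2a3 (2.74 ± 0.58, adjusted p = 0.0312). The glycolysis call ended without KO_s 3 (0.0525). Proliferation genes were lower in KO+s, median -0.21 (adjusted p = 0.00286, 0.779 with an estimated correlation). Aurkb was the 1 member that passed by either adjustment (-0.67 ± 0.16, adjusted p = 0.0405). Oxidative phosphorylation genes had a median of -0.12 with 0 of 74 members passing (adjusted p = 0.0461, adjusted p = 0.917 with an estimated correlation). Of the 6 libraries, 4 each ended that call when left out (0.111 to 0.486). Hepatocyte genes were called lower (adjusted p = 0.00336, adjusted p = 0.102 with an estimated correlation). Their values had a median of -0.49 and a mean of -3.07 over 7 members, 0 up and 1 down (0 and 3 when adjusted over the list alone). Rbp4 in KO+f exceeded KO+s by a ratio of 260.7 (88.89 to 1267).

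HSC identity genes were not called between both forms (adjusted p = 0.832, median -0.01, test direction up), and 2 members rose and 2 fell. Cdkn1c was higher in KO+s (1.51 ± 0.27, adjusted p = 0.0158). Gprasp2 (-5.10 ± 0.70, adjusted p = 0.00679) and Ctnnal1 (-1.44 ± 0.31, adjusted p = 0.0303) were lower. In the MLL-AF9 programme (adjusted p = 0.468) Pbx3 was the 1 member that passed, lower in KO+s at 11.2 against 161 CPM (-3.84 ± 0.69, adjusted p = 0.0179). Flt3 stood at 34.3 against 262 CPM and did not pass (-2.94 ± 1.05, adjusted p = 0.131). Igf2bp3 (-1.43 ± 0.20, adjusted p = 0.00668) and Lin28a (-2.65 ± 0.57, adjusted p = 0.0341) were lower in KO+s. Fam123a (5.003 ± 0.59, adjusted p = 0.00489), Fpr2 (3.85 ± 0.61, adjusted p = 0.0115) and Sept5 (2.93 ± 0.35, adjusted p = 0.00489) were among the genes most raised. Col6a3 (-8.03 ± 1.08, adjusted p = 0.00647), Cgnl1 (7.17 ± 3.40 against 362 ± 250.1 CPM, -5.65 ± 0.67, adjusted p = 0.00489), Ranbp17 (-5.95 ± 0.87, adjusted p = 0.00832) and Gcnt4 (-5.80 ± 0.98, adjusted p = 0.0149) were among those most lowered. Stra6 in KO+f stood above KO+s by a ratio of 446.2 (152.4 to 2166). The gene count was 37 without KO_s 1 (20 up, 17 down), 69 without KO_s 3 (38 and 31) and 129 without KO_f 3 (64 and 65). It was 330 without KO_f 2, where the majority turned (117 up, 213 down), and DESeq2 called 1406 (687 up, 719 down). Of 44 named genes that passed, 13 passed in every leave-one-out fit, including S100a9, Chi3l1, Csf3r, Lyz2, Itgam, Igf2bp3, Ddx58, Col6a3 and Cgnl1. The number was 34, 29 and 22 without KO_f 1, 2 and 3, and 14, 36 and 21 without KO_s 1, 2 and 3.

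Which genes did both add-backs share, and did they run against the loss of Prdm16? Of 12958 genes, 766 rose in both KO+f and KO+s (141.4 under independent lists) and 465 fell in both (94.23 independent). Simulated groups without effects, against the same shared KO+EV libraries, had a mean of 0.05 and 0 shared calls, but at most 0.15 calls per comparison and direction on average, so this does not measure what shared controls add where effects are real. Among those that rose in both were Hlf, Mef2c, Bcl2, Cx3cr1, H2-Aa and Nfkb1, and among those that fell in both were C1qtnf6, Lin28a, Hdc, Plk1 and Sdha. The 2 sets of changes had a correlation of 0.785 (0.499 simulated) and a covariance of 0.96 (0.07 simulated). Of 117 genes higher in KO+EV than in WT+EV, 44 fell with f-PRDM16 (5.138 independent) and 61 with s-PRDM16 (19.38 independent), including C1qtnf6 and Clec3a. Of 155 genes lower in KO+EV, 66 rose with f-PRDM16 (10.67 independent) and 108 with s-PRDM16 (24.57 independent), including Nr4a1, Ier2, Nlrp3 and Zc3h12c. The correlation of the loss with each add-back was -0.413 for f and -0.434 for s, not past the -0.498 and -0.499 that shared controls alone gave, and the covariances were -0.281 and -0.428 against -0.07 and -0.071 simulated. To leave out the shared controls, the 3 KO+EV libraries were divided 1 and 2 between both comparisons in each of 6 ways, with a lone library assumed to vary like the other groups. Calls that rose in both KO+f and KO+s then numbered 12 to 594 (1.612 to 199.7 under independent lists) and those that fell in both 3 to 388 (0.419 to 140.1), over the independent value in 6 of 6 ways, with a covariance of 0.683 to 0.971. The covariance of the loss with the add-back was -0.233 to -0.015 for f and -0.419 to -0.191 for s. Genes raised by the loss that fell with f-PRDM16 exceeded independent lists in 3 of the 6 ways, as did genes lowered by the loss that rose with it, and with s-PRDM16 both did so in 4 of 6. Genes higher in KO+EV that rose further exceeded them as well, in 2 of 6 ways for f-PRDM16 and 4 of 6 for s-PRDM16. In 2 of the 6 ways KO+EV against WT+EV had 0 calls (with KO_EV 1 or KO_EV 2 alone). With KO_EV 3 as the lone control of KO+f, those that rose further with f-PRDM16 numbered 72 (25.5 independent), against 29 that fell (18.62 independent).

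What differed between bone marrow HSCs labelled KO and WT? Immediate early genes were lower as a list in the libraries labelled KO, a call lost with an estimated correlation. In edgeR 0 genes passed (1141 at unadjusted p under 0.05, n = 4 and 4), and DESeq2 called 64. Immediate early and stress genes had a median of -1.02 (adjusted p = 1.8e-18, 0.437 with an estimated correlation). Over all genes 0 members passed, against 17 of 24 lower when adjusted over the list alone. The list score differed by -0.88 (exact two-sided permutation p = 0.057), with 7.36 ± 0.12 in libraries labelled KO and 8.24 ± 0.52 in WT. WT 4 scored 7.47, within the 7.19 to 7.48 of the libraries labelled KO, against 8.41 to 8.61 in the other WT libraries. Its Fos level was 1781 CPM, against 1543 to 1777 in the libraries labelled KO and 3448 to 4277 in the other WT libraries. Fos was 1658 against 3379 CPM (-1.03 ± 0.24, adjusted p = 0.478), Ier3 110.0 ± 27.4 against 238 ± 54.8 CPM (-1.11 ± 0.22, adjusted p = 0.478), Btg2 104 against 274 CPM (-1.40 ± 0.31, adjusted p = 0.478) and Ier5 -0.84 ± 0.20. Inflammation and NF-kB genes had a median of -0.29 (adjusted p = 0.000252, adjusted p = 0.732 with an estimated correlation). Of these 0 passed over all genes, against 7 lower when adjusted over the list alone. Socs3 stood at -1.11 ± 0.32 and Gadd45b at -1.30 ± 0.32.

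Ribosomal protein genes were lower as a list (median -0.31, adjusted p = 7.1e-10, 0.910 with an estimated correlation). So were replication histones (median -0.42, adjusted p = 0.000811, 0.910 with an estimated correlation). Oxidative phosphorylation genes (median -0.19, adjusted p = 0.00372, 0.910 with an estimated correlation) were lower too, and 0 members of these 3 lists passed. HSC identity genes (median -0.12, adjusted p = 0.359), granulocyte genes (median 0.60, adjusted p = 0.466) and monocyte and macrophage genes (adjusted p = 0.140) were not called. The genes with the smallest p-values, none passing, were Sertad1 (63.8 ± 7.93 against 129 ± 10.4 CPM, -1.01 ± 0.15, adjusted p = 0.272), Slc5a3 (20.7 ± 2.20 against 7.65 ± 1.17 CPM, 1.44 ± 0.23, adjusted p = 0.283) and Zbtb41 (47.1 against 20.4 CPM, 1.21 ± 0.22, adjusted p = 0.478). Xpo1 (219 against 121 CPM, 0.86 ± 0.17) and Gadd45g (10.6 against 24.0 CPM, -1.18 ± 0.22) followed. Id1 (5.88 against 27.9 CPM, -2.25 ± 0.57), Id3 (-1.81 ± 0.56), Gdf15 (-1.85 ± 0.36), Cdkn1a (-1.34 ± 0.37) and Prtn3 (181 against 277 CPM, -0.62 ± 0.14) had negative values. Hmox1 (18.9 against 6.47 CPM, 1.55 ± 0.38), Vcam1 (1.64 ± 0.51) and Mrc1 (2.53 ± 0.63) had positive ones. The inflammation call ended without WT 1 (0.197). The oxidative phosphorylation call ended without WT 2 (0.161), WT 4 (0.957) or KO 1 (0.0717), and the histone call without WT 4 (0.206) or KO 1 (0.147); 3 genes passed without WT 4.

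What did total Prdm16 loss change in fetal liver HSCs? Granulocyte, monocyte and mast cell genes were higher in KO and HSC identity genes lower as lists by camera with a preset correlation, calls that ended with an estimated correlation (adjusted p = 0.296, 0.0542, 0.151 and 0.233). Single genes passed in edgeR only with the replicate number as block and in DESeq2 without it. In edgeR 0 genes passed without the block (739 at unadjusted p under 0.05, n = 3 and 3), DESeq2 called 76, and the blocked edgeR fit called 176 (82 up, 94 down). The blocked split was 95 up and 43 down with both libraries numbered 1 left out, 42 up and 9 down without number 2, and 145 up and 175 down without number 3. Granulocyte genes had a median of 2.89 (adjusted p = 1.3e-26, adjusted p = 0.296 with an estimated correlation, blocked 1.8e-218). Over all genes 0 of these passed, against 4 up and 0 down when adjusted over the list alone. In the blocked fit Ngp (526 ± 602 against 50.3 ± 53.1 CPM, 3.25 ± 0.13, adjusted p = 0.000532), Chi3l1 (23.1 ± 17.8 against 1.59 ± 1.32 CPM, 3.91 ± 0.19, adjusted p = 9.5e-05), Olfm4 (2.37 ± 0.27, adjusted p = 0.0424) and Cxcr2 (1.78 ± 0.30, adjusted p = 0.0424) rose. Monocyte and macrophage genes had a median of 1.04 (adjusted p = 4.1e-15, adjusted p = 0.0542 with an estimated correlation, blocked 3.8e-20). Over all genes 0 of these passed, against 10 up and 0 down when adjusted over the list alone. Cybb (36.9 against 4.46 CPM, 2.80 ± 0.23, adjusted p = 0.00421), Ccr1 (9.29 against 2.20 CPM, 2.06 ± 0.30, adjusted p = 0.0272), Csf1r (18.1 against 9.07 CPM, 1.02 ± 0.17, adjusted p = 0.0424) and Slc40a1 (2.61 ± 0.29, adjusted p = 0.0146) rose in the blocked fit. Mast cell and basophil genes had a median of 1.19 (adjusted p = 2.2e-07, adjusted p = 0.151 with an estimated correlation, blocked 0.000264). Over all genes 0 of these passed, against 1 up when adjusted over the list alone. The libraries numbered 3 stood apart in the same genes: Mpo was 655.1 CPM in WT 3 and 4797 CPM in KO 3, against 29.86 to 45.02 in the other WT and 179 to 292.2 in the other KO libraries.

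HSC identity genes had a median of -0.24 (adjusted p = 3.2e-06, adjusted p = 0.233 with an estimated correlation, blocked 4.5e-07), with 0 of 38 passing without the block. Hlf (121 ± 20.4 against 175 ± 19.9 CPM, -0.54 ± 0.07, adjusted p = 0.0128) and Mecom (66.8 ± 12.9 against 99.2 ± 14.6 CPM, -0.58 ± 0.07, adjusted p = 0.0151), both transcription factor genes of HSCs, fell in the blocked fit; without the block Hlf was -0.53 ± 0.15, adjusted p = 0.964. Stroma and endothelium genes had a median of -0.20 (adjusted p = 0.0102, adjusted p = 0.509 with an estimated correlation, blocked 0.000373). The basement membrane collagen genes Col4a1 (153 against 237 CPM, -0.65 ± 0.08, adjusted p = 0.0151) and Col4a2 (99.5 against 160.0 CPM, -0.70 ± 0.06, adjusted p = 0.00294) fell in the blocked fit. Cd74 (-0.81 ± 0.09, adjusted p = 0.00725), Itsn1 (-1.02 ± 0.14, adjusted p = 0.0182), Wfdc17 (-0.95 ± 0.10, adjusted p = 0.00688), Gvin1 (-0.86 ± 0.06, adjusted p = 0.000650) and Pcp4l1 (-1.40 ± 0.17, adjusted p = 0.0133) fell there as well, Gvin1 having near-identical copies that may share its reads. F10 (2.95 ± 0.22, adjusted p = 0.000814), Rgs1 (1.83 ± 0.14, adjusted p = 0.000888), Pram1 (2.72 ± 0.19, adjusted p = 0.000650) and F13a1 (94.5 ± 48.5 against 18.99 ± 5.46 CPM, 2.24 ± 0.24, adjusted p = 0.0438) rose, and Sva stood at a ratio of 202.3 (35.92 to 8026).

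Proliferation genes had a median of 0.17 (adjusted p = 1.4e-06, adjusted p = 0.0542 with an estimated correlation, blocked 3.1e-06). Inflammation and NF-kB genes had a median of 0.11 with a mean of 0.42 (adjusted p = 5.9e-05, adjusted p = 0.151 with an estimated correlation, blocked 0.000135). Ribosomal protein genes had a small positive median (0.09, adjusted p = 0.00331, adjusted p = 0.807 with an estimated correlation, blocked 1.3e-05). So had replication histones (0.19, adjusted p = 0.00494, adjusted p = 0.807 with an estimated correlation, blocked 0.00245). Oxidative phosphorylation genes (0.07, adjusted p = 0.00778, adjusted p = 0.807 with an estimated correlation, blocked 0.00115) went the same way. Megakaryocyte and platelet genes (0.36, adjusted p = 0.00778, adjusted p = 0.807 with an estimated correlation, blocked 0.00154) were called up. So were glycolysis genes (0.14, adjusted p = 0.0408, adjusted p = 0.807 with an estimated correlation, blocked 0.00439). The MLL-AF9 programme was called down (-0.16, adjusted p = 0.00437, adjusted p = 0.509 with an estimated correlation, blocked 0.00156). Without the block 0 members of these lists passed over all genes, and 1 inflammation gene was up when adjusted over the list alone. The block alone called the interferon response lower (blocked median -0.16, 9.4e-05, unblocked 0.116, adjusted p = 0.212 with an estimated correlation) and the fetal HSC programme lower (-0.24, 0.00245, unblocked 0.0821, adjusted p = 0.416 with an estimated correlation). It called lymphoid genes higher by camera with a blocked median of -0.01 and a mean of 0.33 (0.0261, unblocked 0.558, adjusted p = 0.436 with an estimated correlation). The glycolysis call ended without WT 3 (0.403, direction turned), KO 1 (0.679) or KO 2 (0.165). The megakaryocyte call ended without WT 3 (0.702), KO 1 (0.274) or KO 2 (0.860), the MLL-AF9 call without KO 3 (0.162), and the stroma call without WT 1 (0.112), WT 2 (0.0743) or KO 3 (0.394). Without WT 1, WT 2 or KO 3 the adjusted p-values were 0.917, 0.0570 and 0.429 for oxidative phosphorylation, 0.142, 0.622 and 0.696 for histones, and 0.850, 0.0929 and 0.361 for ribosomal genes. The direction turned without KO 3 in all 3 and without WT 1 in the ribosomal list.

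What did loss of f-PRDM16 change in fetal liver HSCs? HSC identity genes were lower and granulocyte genes higher in KO as lists, calls lost with an estimated correlation. In edgeR 0 genes passed (357 at unadjusted p under 0.05, n = 3 and 3), with 0 in the blocked fit (1716 unadjusted) and 1 in DESeq2. With both libraries numbered 1 left out the blocked fit called 236, and 0 without number 2 or number 3. Without the block 0 members of any list passed, over all genes or adjusted over the list alone. HSC identity genes had a median of -0.80 over 38 members (adjusted p = 1.2e-16, adjusted p = 0.505 with an estimated correlation, blocked 6.9e-28). The list score was lower in KO in all 3 numbered pairs, by 0.73 on average (exact two-sided permutation p = 0.2). Fgd5 was 28.6 ± 3.33 against 59.0 ± 21.7 CPM (-1.04 ± 0.27, adjusted p = 0.999; blocked -0.98 ± 0.21, adjusted p = 0.237), Mecom 38.7 ± 19.4 against 79.8 ± 41.0 CPM (-1.04 ± 0.52, adjusted p = 0.999; blocked -1.02 ± 0.11, adjusted p = 0.101). Mmrn1 was 24.3 against 42.7 CPM (-0.81 ± 0.26), Angpt1 102 against 153 CPM (-0.58 ± 0.19) and Meis1 95.4 against 160.5 CPM (-0.75 ± 0.32). Granulocyte genes had a median of 1.59 (adjusted p = 1.2e-16, adjusted p = 0.505 with an estimated correlation, blocked 9.5e-15), the score being higher in KO in 3 of 3 pairs (exact two-sided permutation p = 0.2). Mmp9 was 20.8 against 6.14 CPM (1.76 ± 0.56) and Ms4a3 397 against 149.5 CPM (1.41 ± 0.66). Mpo was high in WT 3, KO 2 and KO 3 (9505, 12940 and 25580 CPM) against 1520 to 5603 in the others.

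Megakaryocyte and platelet genes had a median of -0.16 (adjusted p = 0.0122, 0.590 with an estimated correlation, blocked 0.00824). Vwf stood at 2.18 ± 1.03 against 15.9 ± 10.8 CPM (-2.86 ± 0.66, adjusted p = 0.999; blocked -2.69 ± 0.33, adjusted p = 0.107). Stroma and endothelium genes had a median of -0.46 (adjusted p = 0.00440, 0.505 with an estimated correlation, blocked 5.1e-06). Col4a1 stood at 113 against 232 CPM (-1.04 ± 0.54; blocked -1.02 ± 0.08, adjusted p = 0.101) and Col4a2 at 83.2 against 194 CPM (-1.22 ± 0.52). Rasip1 (17.7 against 54.9 CPM, -1.63 ± 0.89), Tgfbr3 (30.9 against 81.4 CPM, -1.40 ± 0.45) and Slc6a17 (-3.08 ± 0.64) also had negative values, and WT exceeded KO in Tfcp2l1 by a ratio of 37.22 (9.973 to 312.6). Mast cell and basophil genes (1.00, adjusted p = 6.7e-07, adjusted p = 0.505 with an estimated correlation, blocked 2.4e-05) were called up. So were monocyte and macrophage genes (0.68, adjusted p = 0.000238, adjusted p = 0.505 with an estimated correlation, blocked 0.00225) and proliferation genes (0.11, adjusted p = 0.000249, adjusted p = 0.590 with an estimated correlation, blocked 0.000261). Ribosomal protein genes (0.12, adjusted p = 7.2e-07, adjusted p = 0.594 with an estimated correlation, blocked 5.1e-06) were called up, as were oxidative phosphorylation genes (0.10, adjusted p = 0.000155, adjusted p = 0.590 with an estimated correlation, blocked 0.000261). Erythroid genes (0.62, adjusted p = 0.0106, adjusted p = 0.608 with an estimated correlation) and lymphoid genes (0.34, adjusted p = 0.0327, adjusted p = 0.562 with an estimated correlation) lost their calls with the block (0.0651 and 0.0959). Glycolysis (0.20, adjusted p = 0.0191, adjusted p = 0.671 with an estimated correlation, blocked 0.00453) and brown fat genes (0.48, adjusted p = 0.0245, adjusted p = 0.562 with an estimated correlation, blocked 0.00584) were called up.

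The fetal HSC programme was called down (-0.47, adjusted p = 0.00472, adjusted p = 0.505 with an estimated correlation, blocked 2.2e-05). The MLL-AF9 programme was lower (-0.22, adjusted p = 0.00543, adjusted p = 0.505 with an estimated correlation, blocked 0.00248), and so was the interferon response (-0.47, adjusted p = 0.00853, adjusted p = 0.671 with an estimated correlation, blocked 0.00434). Immediate early genes were called down as well (-0.27, adjusted p = 0.0322, adjusted p = 0.671 with an estimated correlation, blocked 2.1e-06). The megakaryocyte call ended without WT 3 (0.268), KO 1 (0.292) or KO 2 (0.387), and those of stroma and fetal HSC genes without WT 3 (0.180 each) or KO 1 (0.108 and 0.0661). Proliferation lost its call without WT 3 (0.165) or KO 1 (0.0661), and immediate early genes without WT 3 (0.530, direction turned), KO 1 (0.543) or KO 2 (0.908). The interferon list turned direction without WT 2 (1.3e-05, called up) and was not called without KO 1 (0.282) or KO 3 (0.163). Erythroid genes lost their call without WT 1 (0.388), KO 2 (0.697) or KO 3 (0.157), lymphoid genes without WT 1 (0.0652) or KO 2 (0.697), and brown fat genes without WT 1 (0.0512), WT 2 (0.175) or KO 3 (0.0762). Oxidative phosphorylation lost it without KO 2 (0.0569), and glycolysis without WT 1 (0.516), WT 2 (0.0852) or KO 3 (0.400, direction turned).

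**Figure D3:**
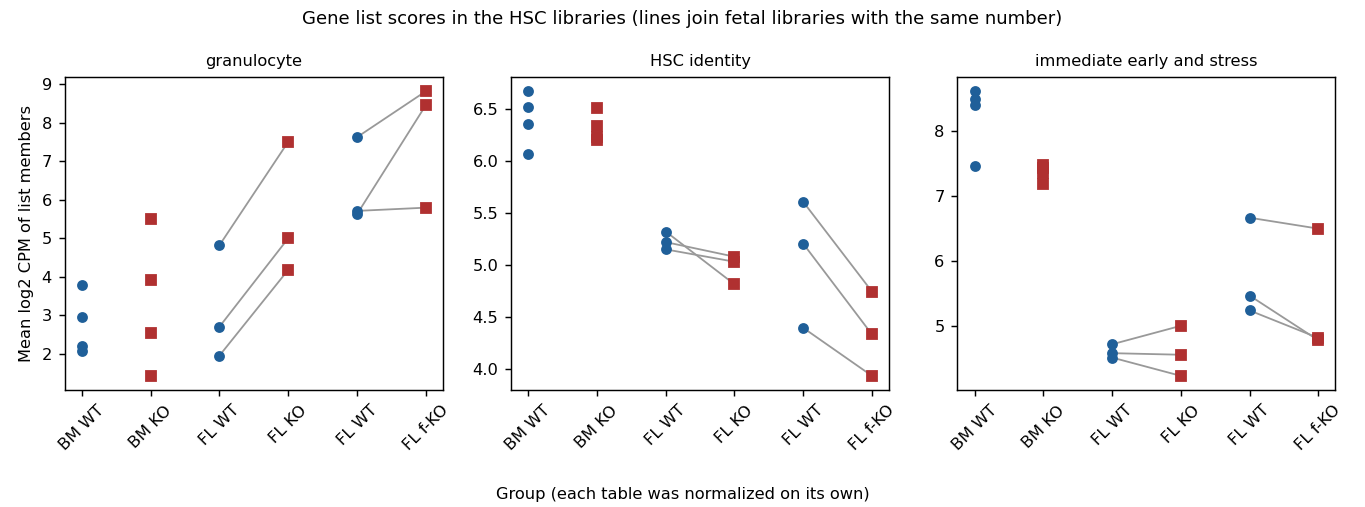
Mean log2 CPM of granulocyte, HSC identity and immediate early genes per HSC library, each table normalized on its own, with lines joining fetal libraries of the same number. The KO minus WT difference in the granulocyte score was 2.40 in total-knockout and 1.37 in f-PRDM16-knockout fetal HSCs.

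Did the HSC comparisons differ from each other? The difference between the bone marrow contrast (libraries labelled KO against WT) and the fetal total-knockout effect passed for 1 gene, Slc5a3 (2.11 ± 0.28, adjusted p = 0.0373), a transporter gene, with 1268 genes at unadjusted p under 0.05 and 33 calls in DESeq2. No gene passed in edgeR with a block within each table. Slc5a3 passed in the leave-one-out fits without BM_WT 3 or BM_WT 4 and in none of the others. Immediate early genes (-0.88, adjusted p = 2.4e-08, adjusted p = 0.288 with an estimated correlation) were lower in the bone marrow contrast than in the fetal effect, where the list was not called (median 0.00, adjusted p = 0.974). Granulocyte genes (-1.42, adjusted p = 0.000836, adjusted p = 0.696 with an estimated correlation) and monocyte genes (-1.21, adjusted p = 0.0102, adjusted p = 0.288 with an estimated correlation) were lower in the bone marrow contrast too, where neither list was called. HSC identity genes had a median difference of 0.24 (adjusted p = 0.0249, adjusted p = 0.647 with an estimated correlation). The granulocyte difference was not called without FL_KO 3 (0.248), the monocyte difference without BM_WT 1 (0.0849) or FL_KO 3 (0.0722). The HSC identity difference was not called without BM_WT 4 (0.289), BM_KO 3 (0.179), FL_WT 3 (0.185) or FL_KO 3 (0.0677). Between the f-PRDM16 and the total knockout in fetal liver 0 genes passed in edgeR (335 at unadjusted p under 0.05) and 0 in DESeq2. HSC identity genes (-0.44, adjusted p = 2.3e-05, adjusted p = 0.852 with an estimated correlation) were lower in the f-PRDM16 effect. So were megakaryocyte (-0.74, adjusted p = 7.7e-05, adjusted p = 0.852 with an estimated correlation) and monocyte genes (-0.67, adjusted p = 0.000954, adjusted p = 0.852 with an estimated correlation). Granulocyte genes were not called (-1.27, adjusted p = 0.0547; blocked 4.8e-05, adjusted p = 0.754 with an estimated correlation). The block within each table also called the fetal HSC programme (-0.41, unblocked 0.0890, blocked 0.00282, adjusted p = 0.422 with an estimated correlation) lower. Immediate early (-0.34, unblocked 0.175, blocked 4.8e-05, adjusted p = 0.549 with an estimated correlation) and stroma genes (-0.42, unblocked 0.156, blocked 0.0276, adjusted p = 0.422 with an estimated correlation) were called lower there too. With multi-copy entries removed and no block, granulocyte genes (median -1.22, adjusted p = 0.0122) and the fetal HSC programme (-0.38, adjusted p = 0.0497) were called lower (adjusted p = 0.964 each with an estimated correlation). The HSC identity difference was not called without FL47_WT 2 (0.0580), the megakaryocyte difference without FL_WT 3 (0.121) or FL_KO 2 (0.208), and the monocyte difference without FL47_WT 1 (0.478) or FL47_KO 2 (0.123). Prdm16 itself did not differ in either contrast (0.77 ± 0.66, adjusted p = 0.794 and -0.69 ± 0.49, adjusted p = 1.00).

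More genes moved alike in both fetal tables than independent genes would give, at unadjusted p only, since at adjusted p the overlap was 0. Exchanged labels were not run for this overlap, and many genes follow a structure of the samples other than the labels. Chance is therefore not excluded. Of 12723 genes, 14 were up in both (2.658 expected, two-sided Fisher exact p = 3.86e-07) and 49 down in both (5.857 expected, p = 1.3e-31), Fisher's test treating genes as independent. Prdm16 was among the 49. With the block, 199 were up (42.11 expected) and 367 down (92.16 expected), the latter including Mecom, Col4a1 and Col4a2. Bone marrow and the total-knockout fetal table shared 11 up (13.69 expected) and 17 down (11.97 expected), and bone marrow and the f-PRDM16-knockout table had in common 10 up (4.891 expected, Fisher exact p = 0.0306) and 10 down (8.729 expected, p = 0.601). Replicate numbers did not pair the bone marrow libraries, so their unblocked fit was also set against the blocked fetal fits. It then shared 38 up (29.55 expected, two-sided Fisher exact p = 0.121) and 69 down (38.95 expected, p = 2.28e-06) with the f-PRDM16 knockout. With the total knockout it shared 32 up (41.06 expected, Fisher exact p = 0.158) and 30 down (42.49 expected, p = 0.0402), both below expectation.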

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

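The interactions were planned tests, and the far-sample rule was fixed before the data were examined; the splits named here were tests chosen only after the result was seen. In the groups of 4, 264 sets of values were tested for a sample far from the others, and 7 held one, while chance marks about 1 in 20. In the bone marrow libraries labelled KO these were the interferon response score of library 2 (5.3564, others 5.4643 to 5.4764), Fn1 in library 4 (13.04 CPM, others 2.801 to 4.398), Mest in library 4 (13.12 CPM, others 5.591 to 6.767) and Gata2 in library 3 (548.2 CPM, others 598.4 to 606.5). In bone marrow WT they were H2-DMa in library 1 (193.2 CPM, others 309.2 to 329.4), and in library 2 Hdac2 (142.0 CPM, others 204.5 to 216.2) and Hk2 (71.26 CPM, others 46.47 to 49.2).

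The contrast of bone marrow libraries labelled KO against WT differed from the total-knockout effect in fetal liver, by interaction tests, in Slc5a3 (2.112) and in 12 lists by camera. Medians of the difference were -0.883 for immediate early and stress, -0.396 for ribosomal proteins, -0.578 for replication histones, -1.424 for granulocyte, -0.491 for inflammation and NF-kB, and -1.789 for mast cell and basophil genes. They were -0.242 for oxidative phosphorylation, 0.261 for the MLL-AF9 programme, -0.201 for proliferation, -1.211 for monocyte and macrophage, 0.238 for HSC identity and -0.467 for megakaryocyte and platelet genes. With an estimated correlation none of the 12 was called (adjusted p = 0.288 to 0.764). Leaving out 1 library also ended some calls, in addition to those given above for granulocyte, monocyte and HSC identity genes. Oxidative phosphorylation was lost without BM_WT 2 (0.0950), BM_WT 4 (0.377), FL_WT 1 (0.0894) or FL_KO 3 (0.234), and proliferation without BM_WT 4 (0.398) or BM_KO 3 (0.104). The MLL-AF9 programme was lost without BM_WT 4 (0.0792) and inflammation without BM_WT 1 (0.0529). Megakaryocyte genes were lost without BM_WT 1 (0.107), BM_KO 4 (0.0955), FL_WT 3 (0.593), FL_KO 1 (0.274) or FL_KO 2 (0.741). Of 100 splits of the libraries 11 called as many genes as the real labels did (1 gene; highest other 3). Those splits exchange labels without regard to the pairing of the fetal libraries, and no gene passed in edgeR with a block within each table (33 in DESeq2 without it). In that blocked fit, 2 of the 64 splits that part every pair, the real one included, reached the 1720 genes at unadjusted p under 0.05 (highest other 1849). That share is under 0.05, but not every bone marrow pair exceeded a correlation of 0.1, so chance is not firmly excluded.

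The f-PRDM16 effect differed from the total-knockout effect in fetal liver in 4 lists: hepatocyte (median 3.302), HSC identity (-0.438), megakaryocyte and platelet (-0.743), and monocyte and macrophage (-0.673). None was called with an estimated correlation (adjusted p = 0.852 each). Many hepatocyte members were near 0 counts, and the hepatocyte call ended without FL47_KO 3 (0.847) or FL_KO 3 (0.167). With multi-copy entries removed, 2 more lists were called, granulocyte (0.0122) and fetal HSC genes (0.0497), with adjusted p = 0.964 each with an estimated correlation. At unadjusted p 335 genes differed, and 79 of 100 splits gave as many, the highest being 3387, which points to a structure of the samples other than their labels. Those splits and that count leave the pairing out; 980 genes differed at unadjusted p with a block within each table, and 10 of the 32 splits that part every pair of both tables gave as many, so chance is not excluded. The highest of those (3577) exchanges all labels of the total-knockout table, so that both knockout effects add up in it.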

How the results depend on the processing

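The alternatives were fixed before the data were examined, except the removal of multi-copy entries, blocks with both libraries of a number left out, the block within each table for interactions, overlaps at unadjusted p, and the division of the KO+EV libraries, which were chosen after seeing the data. Every alternative was run, and the cause of the changes below was not tested. Of 85 list calls, RLE size factors and robust off kept 85, the strict filter 83, no filter 81, fry 20 and an estimated correlation 0. RLE size factors, both filters and robust off moved no count of calls by over 1.5 times. DESeq2 called 907 (KO+EV against WT+EV), 2267 (KO+f against KO+EV), 1406 (KO+s against KO+f), 64 (bone marrow), 76 (total-knockout fetal), 1 (f-PRDM16-knockout fetal) and 33 (bone marrow minus fetal). Fits of the 2 compared groups alone called 1 gene for KO+EV against WT+EV and 392 for KO+f against KO+EV. Calls shared between HSC tables went from 0 to 111 at unadjusted p and to 734 with the block, or 735 with the block in the fetal tables only.

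Leaving out 1 library gave 26 to 425 calls for KO+EV against WT+EV, 559 to 1533 for KO+f, 2732 to 3821 for KO+s, and 37 to 388 for KO+s against KO+f. It gave 0 to 3 in bone marrow, 0 in each fetal table, 0 to 2 for bone marrow minus fetal, and 0 to 3 for the difference of the fetal effects. Prdm16 ranged from -4.46 to -3.15 in KO+EV against WT+EV (adjusted p from 0.0349 to 0.0818), 11.72 to 13.03 for KO+f, 11.61 to 12.92 for KO+s, and -0.314 to 0.0791 for KO+s against KO+f. It ranged from -0.32 to 0.35 in bone marrow, -0.96 to -0.49 in total-knockout and -1.71 to -1.07 in f-PRDM16-knockout HSCs. Lists that turned direction had adjusted p-values, lowest and highest, of 1.8e-05 and 0.679 (glycolysis), 2.3e-07 and 0.917 (oxidative phosphorylation), 1.3e-07 and 0.696 (histones) and 1.1e-12 and 0.850 (ribosomal) in the total-knockout fetal table. In the f-PRDM16-knockout table they were 4.9e-06 and 0.516 (glycolysis), 2.8e-12 and 0.908 (immediate early) and 3.2e-06 and 0.282 (interferon response). Counting each list call once per left-out library, 545 stayed, 87 were lost and 8 turned direction.

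With the replicate number as a block, or pairing, the total-knockout fetal table called 176 genes, and 138, 51 and 320 with both libraries numbered 1, 2 or 3 left out, or 174 without multi-copy entries. Prdm16 there was -0.82 (adjusted p = 0.0302), -0.94 (0.0530), -0.87 (0.227) and -0.67 (0.0119) without number 1, 2 or 3, and -0.82 (0.0295) without multi-copy entries. The blocked f-PRDM16-knockout table called 236 genes without number 1, with Prdm16 at -1.55 (0.0494), and 0 without number 2 or number 3, where Prdm16 did not pass (0.620 and 0.840); without number 2 its interferon list turned direction (0.690). The block within each table left 0 calls for bone marrow minus fetal and called its interferon list (0.0403, adjusted p = 0.528 with an estimated correlation). In leukaemia the correlation of same-number libraries was 0.026, 0.043 and 0.047 for KO+EV against WT+EV, 0.063, -0.182 and -0.017 for KO+f, 0.021, -0.050 and -0.019 for KO+s, and 0.039, 0.289 and -0.025 for KO+s against KO+f. In bone marrow it was 0.203, 0.031, 0.043 and -0.032, and not every sample correlated best with its own number. The block gave 195, 1442, 4177 and 372 calls in leukaemia and Prdm16 at 0.06 in bone marrow. It ended the proliferation call of KO+EV against WT+EV (adjusted p = 0.0523), called MHC class II up in KO+s (0.0140, adjusted p = 0.552 with an estimated correlation) and mast cell genes down in bone marrow (0.00793, adjusted p = 0.864 with an estimated correlation), and changed no other list call in those tables. In the f-PRDM16 knockout it ended the erythroid (0.0651) and lymphoid (0.0959) calls.

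Depth was at least 16.4 M counts, and it limits genes such as Prdm16 in KO+EV, where 3 counts in a library of that group stand for about 0.15 CPM.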

Other observations

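The tests of explanations and the splits in this part were chosen only after the result was seen, except the heat shock tests. Set against WT+EV, 1292 genes passed in KO+f and 3072 in KO+s (edgeR, n = 3 each). Granulocyte genes had a median of -0.44 in KO+f (adjusted p = 0.00582, adjusted p = 0.574 with an estimated correlation) and 0.97 in KO+s (adjusted p = 0.000512, adjusted p = 0.743 with an estimated correlation). Immediate early genes had a median of -0.98 in KO+f (adjusted p = 0.00859, adjusted p = 0.703 with an estimated correlation) and 0.16 in KO+s (adjusted p = 0.853). Of 117 genes raised in KO+EV, 45 in KO+f and 48 in KO+s were still above WT+EV; of 155 lowered, 64 and 49 were still below. The library KO_EV 3 stood apart from the other KO+EV libraries (chi-square per degree of freedom 138 and 151, against 15.1 between those).

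Granulocyte genes were higher in KO of both fetal tables. In the total-knockout table the 27 members without near-identical copies had a median of 2.851 ± 0.272. Leaving out so few members could hardly move it, so it only shows that these 27 rose without such copies. Granulocytic cells among sorted cells would raise nearly all members, and at least 96.77% were above 0 in both tables, which goes with such cells. The same would be seen if the sorted cells themselves expressed these genes, although the gate (Lin-, CD48-) was set to leave mature cells out. An effect of the genotype stays open and untested.

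Immediate early genes were lower in bone marrow libraries labelled KO, a call lost with an estimated correlation. A single library is argued against (highest list median with 1 left out -0.855). Stress of dissociation and sorting that raises heat shock genes could have differed between groups. The median of 10 such genes was 0.103 ± 0.201. That met the bound written against stress, but cannot decide, because members went both ways (4 of 10 below 0). Dnajb1 was -0.65 ± 0.25, but Chordc1 0.70 ± 0.21 and Dnaja1 0.54 ± 0.18 (adjusted p = 0.521 to 0.540). Stress and genotype stay open. Prdm16 RNA did not bear out the labels here. A count over the whole gene cannot test a deletion of part of it, so this does not decide about the labels.

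Immediate early genes were also lower in leukaemia KO+EV than in WT+EV, a call lost with an estimated correlation. A single library is argued against, the highest median with 1 library left out being -1.573. The heat shock median was 0.157 ± 0.193 and met the bound written against stress, yet members went both ways (4 of 9 below 0) and Dnajb1 fell (-0.55 ± 0.12, adjusted p = 0.0450, 60.1 against 88.1 CPM). Stress and genotype therefore stay open.

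Other splits of the same libraries were fitted in the same way. The real labels gave 272, 1461, 4200 and 494 calls in the 4 leukaemia comparisons, the highest other split 1, 0, 0 and 0; only 1 of 10 splits, the real one, reached each real count, and 10 splits are too few for a share under 0.05. In bone marrow 4 of 35 splits reached the 1141 genes at unadjusted p under 0.05, with 1768 at most. Among fetal libraries 5 of 10 splits in each table reached the real counts of 739 (highest 3295) and 357 (highest 2692, with 153 calls). Many genes thus follow a structure of the samples other than the labels. That structure matches Mpo: WT 3, KO 2 and KO 3 of the f-PRDM16-knockout table stood against the rest. With the block, among the 4 splits that part all pairs the real labels gave most genes, 1 of 4 in each table: 2240 against 315 at most in the total knockout and 1716 against 711 in the f-PRDM16 knockout. The other splits exchange both labels within 1 pair, and 4 splits are too few for a share under 0.05.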
